A study of Arabidopsis thaliana with 6 samples.

How the data were processed

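Total RNA of 6 leaf samples was analysed, 3 egg-deposited and 3 untreated. Per the labels' protocols, the plants were 7 weeks old, grown at 20 °C in short days (6 weeks with 10 h of light and 14 h of dark, then a week with 8 h and 16 h), and a single cluster of about 40 eggs was placed on the underside of a leaf between positions 14 and 17. Cy3-labelled cRNA was hybridised to one-colour Agilent arrays. Per the file headers, the scanner intensity values were extracted with Feature Extraction 11.5.1.1, while the submitters' processing notes name Agilent Feature Extraction 10.1. The processed signal is a linear intensity that was background-subtracted and detrended within each array, per the file headers, and no scaling between arrays had been applied. The deposited series table holds the authors' log2 values. Each of its columns correlated best with its own array (r from 0.987 to 0.989 across spots, which are not independent replicates), and the column medians were 6.47, 6.48, 6.47, 6.47, 6.48 and 6.47 in the order untreated 1 to 3 and egg-deposited 1 to 3. Its scale is therefore close to log2 of the signal, how it was normalized is not given in the sources used here, and it served as an alternative only.

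Each array held 62976 spots, of which 61657 were not controls and read 59017 probes. No spot was saturated, and 18 to 81 spots per array were marked as outliers and left out. The 75th percentile of the signal ranged from 368 to 503 between arrays. Log2 of the processed signal minus the array's 75th percentile was used. Spots of a probe were averaged, and 105 probes with an outlier on every spot of an array were dropped. The probes name 30541 loci, of which 29870 matched the reference table (assembly TAIR10.1), which was used for symbols only; coordinates are those of the array design, build TAIR10. The probe with the highest mean over all 6 arrays stood for its gene, and a gene was tested if that probe was well above background on at least 3 of the 6 arrays. Of the called genes, 106 had more than 1 tested probe, and in 1 of these a probe had the opposite sign.

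The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Gene lists with at least 5 tested members were tested with camera at its preset inter-gene correlation of 0.01, with adjustment over the 24 lists. Beside it camera with an estimated correlation, fry, and the percentile of the median among 10000 random lists of matched signal were computed. Before the data were examined, the lists, the tests, the alternatives and the rule for named genes were fixed. By that rule the named genes are the 10 largest rises and 10 largest falls among called genes without overlap and well above background on at least 2 arrays of each group, the 3 largest lower bounds in each direction, the egg response markers with VSP2 and PDF1.2a, and up to 4 members with the smallest p of each list described. IGPS, EDS1, PAD4 and BIP3 were named after their values were seen, to fill out a count, as were the members of enriched families and of the added lists. Where the probe standing for a gene was not well above background on any array of a group, the fold is a lower bound, the mean of the bright group against the mean of, per array, the higher of the gene's own value and the lowest value among probes well above background. No list member was dropped for a locus that did not match.

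Correlations between arrays over the tested genes were 0.969 to 0.981 within untreated, 0.960 to 0.983 within egg-deposited and 0.916 to 0.966 between the groups, so no array repeated another. Replicate numbers come from the sample titles. The deviations of same-numbered arrays from their group means correlated at 0.40 (replicate 1, on a shared slide), 0.13 and 0.33, so the numbers were taken to pair the samples. Slide and scan day were read from the headers. Scan day was fitted as a block; a slide term leaves no residual degrees of freedom, and a random slide effect could not be estimated because only 1 slide holds 2 arrays.

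The procedure was tested on simulated data with the real means of the 19626 genes and 200 changed genes in each of 10 runs. It recovered 38.7% of the genes changed 2-fold, 79.4% of those changed 4-fold and 94.4% of those changed 16-fold in the simulated egg-deposited against untreated comparison, with 5.5% of the calls false. A list of 20 genes shifted 2-fold was found in 10 of 10 runs. The simulated genes were uncorrelated, so this says nothing about correlated lists. Their variances were drawn without regard to signal and no simulated array stood apart, so the rates of recovery and of false calls may not hold for the real arrays. Alternatives covered normalization, background correction, the filter on dim probes, several probes per gene, the variance prior, array weights, blocks, each array left out, the test and the threshold. Figures were drawn with matplotlib 3.10.9.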

Results

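Gene expression was measured in rosette leaves of Arabidopsis thaliana Col-0, the common laboratory wild type, after eggs of the large white butterfly (Pieris brassicae) had been laid on them. Leaf tissue from near the egg cluster of 3 egg-deposited samples was compared with leaf tissue of 3 untreated samples, 6 days after egg deposition. The comparison addressed which transcripts differ in leaf tissue that has carried insect eggs. Each sample was hybridised to 1 array of one colour, and between 62.3% and 64.0% of the spots on an array were well above background. Of 30541 loci on the array, 19626 genes were tested. The number of arrays, 3 per group, limits the precision. The labels do not state that the replicates came from separate plants, so the p-values measure the spread between these samples.

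EXT4 (AT1G76930), which encodes the cell wall protein extensin 4, rose 39.7-fold (log2 fold change 5.31, SE 0.24, limma adjusted p = 0.00183). Its normalized log2 signal was -4.75 ± 0.47 (SD, n = 3) in untreated leaves and 0.57 ± 0.08 (SD, n = 3) in egg-deposited leaves. CYP71A12 (AT2G30750), a cytochrome P450 of indolic compound synthesis, rose 23.7-fold (SE 0.57 on the log2 scale). MSRB9, a methionine sulfoxide reductase, rose 12.6-fold and RLP20, a receptor-like protein, 11.9-fold. TI1, a trypsin inhibitor, rose 10.0-fold, and AT4G12500, of the lipid transfer protein superfamily, 6.96-fold. AT5G44575 and AT1G58225, of unknown function, rose 10.8-fold and 10.7-fold, and AT1G13340 and AT4G39320, annotated as a regulator of Vps4 activity and as related to microtubule-associated proteins, 6.90-fold and 6.88-fold. On every egg-deposited array each of these 10 genes exceeded every untreated array, as the rule for naming them required.

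For genes not well above background on any untreated array, only a lower bound of the fold can be given. AT4G38080, annotated as a hydroxyproline-rich glycoprotein, was at least 74.5-fold higher in egg-deposited leaves (adjusted p = 0.00183). AT3G22620, of the lipid transfer protein superfamily, was at least 57.4-fold higher (adjusted p = 0.0101). CYP71A13, which acts in camalexin synthesis, was at least 51.2-fold higher by its brightest probe (adjusted p = 0.0255). Its other tested probe had a log2 fold change of 4.67, below that bound of 5.68 on the log2 scale, so the bound holds for the brightest probe only. In the array design (TAIR10), the spans given are 17883012 to 17883398 on chromosome 4 for AT4G38080 and 8008615 to 8009415 on chromosome 3 for AT3G22620. CYP71A13 spans 13109909 to 13112006 on chromosome 2, next to CYP71A12 at 13099486 to 13101389. Whether the probes of these closely related neighbours read each other's transcripts was not checked.

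With all arrays in the fit, fewer genes fell than rose. PIN7 (chromosome 1, 8180768 to 8183406), an auxin efflux carrier, fell by 1.42 on the log2 scale (SE 0.13, adjusted p = 0.0210), from 1.99 ± 0.19 to 0.57 ± 0.11 (SD, n = 3 each). BES1, a transcription factor of brassinosteroid signalling, fell by 0.97, and MES18, a methyl esterase, by 1.12. The zinc finger protein gene AT2G26695 fell by 2.29, AT5G62280, of unknown function, by 2.21, and the DnaJ-domain gene AT1G72416 by 2.18. AT3G22142, of the lipid transfer protein superfamily, fell by 1.43, and AT1G18265, AT5G26010 and AT3G10120 by 1.31, 1.27 and 1.12. AT2G07692, not well above background on any egg-deposited array, was at least 3.48-fold lower (adjusted p = 0.00510). The F-box gene AT3G59250, dim on the same arrays, was 1.87-fold lower (adjusted p = 0.0453), where the bound equals the estimate itself. With normexp background correction neither gene passed (limma adjusted p = 0.0934 for AT2G07692 and 0.467 for AT3G59250).

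In total 184 of the 19626 genes differed (limma, Benjamini-Hochberg adjusted p under 0.05), 162 higher and 22 lower in egg-deposited leaves, and 164 changed at least 2-fold. The median log2 fold change was 2.79 for the higher genes and -1.04 for the lower genes. Of the called genes, 78 were not well above background on any untreated array and 2 on any egg-deposited array. All 184 had non-overlapping groups, as had 34.5% of the tested genes, where chance gives 10%. With the replicate number as a block, 177 genes were called, 119 higher and 58 lower, and 96 of the 184 were among them. Of the genes named above, CYP71A12, RLP20, AT4G12500, AT4G39320, AT5G62280, AT1G18265, AT5G26010, AT3G10120, MES18, BES1 and AT3G59250 did not pass that fit, with adjusted p from 0.0510 to 0.0749.

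The arrays were scanned on 2 days, each with both groups, and 1 slide held 1 array of each group. Scan day 1 held only untreated array 2 and egg-deposited array 3, so a value within it cannot be told apart from these arrays' own levels. The shared slide, with untreated array 1 and egg-deposited array 1, lay within scan day 2 and is not independent of it. The higher genes had a median log2 difference of 2.43 within scan day 1, 2.96 within scan day 2 and 2.82 within the shared slide. For the lower genes these were -0.89, -1.12 and -1.06. The groups of all 184 genes did not overlap, so the direction within a batch was fixed. Their call on these same arrays also favoured a large size, so these values decide nothing about a slide or scan day effect. With scan day as a block 49 genes were called, 48 higher and 1 lower, and of the genes named above only EXT4, MSRB9, AT4G38080, AT3G22620 and AT2G07692 passed. Requiring a signal well above background on all 6 arrays left 17806 genes and no call with limma (lowest adjusted p = 0.0538, 4881 genes with an unadjusted p under 0.05). A test per gene without variance moderation made no call either (lowest adjusted p = 0.211, 3288 genes with an unadjusted p under 0.05). Leaving out 1 array gave 30 to 281 calls: 39 without untreated replicate 1, 232 without untreated 2, 54 without untreated 3, 281 without egg-deposited 1 (133 higher and 148 lower, so the balance turned), 30 without egg-deposited 2 and 109 without egg-deposited 3.

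**Figure D1:**
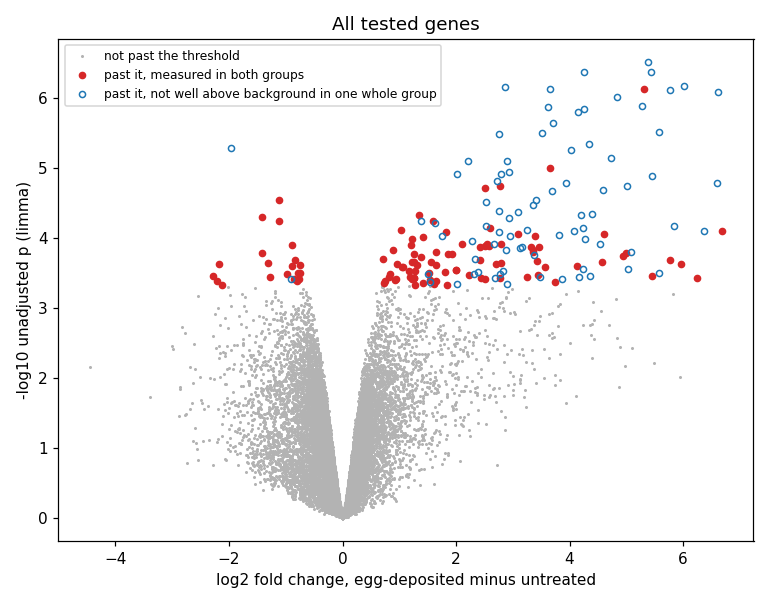
Log2 fold change of egg-deposited against untreated leaves (x axis) and the negative log10 of the unadjusted limma p (y axis) for the 19626 tested genes. Filled red points passed an adjusted p of 0.05 with a signal well above background on at least 1 array of each group, and open blue points passed it without one in a whole group; 162 points past the threshold lie right of 0 and 22 left.

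Markers of the leaf response to eggs, fixed from earlier work, were higher as a group in egg-deposited leaves. Of the 9 tested of 10, 2 rose, none fell and 7 did not pass, while 8 rose adjusted over the list alone. The median log2 fold change was 4.39, or 3.71 with genes at their lower bound, above all 10000 random lists of matched signal (camera adjusted p = 1.51e-06 at the preset correlation, and adjusted p = 0.43 with an estimated correlation). TI1 rose as given above, and FMO1, the flavin monooxygenase that makes the resistance signal N-hydroxypipecolic acid, was at least 13.1-fold higher (adjusted p = 0.0421, 0.0580 with the replicate number as a block and 0.0528 with scan day as a block). PAD3, the last enzyme of camalexin synthesis, had a log2 fold change of 5.82 (SE 0.88, adjusted p = 0.0568), and EDS5, a salicylic acid exporter of the chloroplast, 1.83 (SE 0.30, adjusted p = 0.0697). The pathogenesis-related genes did not pass, with log2 fold changes of 5.94 for PR1 (SE 1.57, adjusted p = 0.114), 4.39 for PR2 (SE 0.86) and 3.24 for PR5 (SE 0.77). CHI, a chitinase, stood at 4.83 (SE 0.97, adjusted p = 0.0835). SAG13, a senescence marker, had -0.45 (SE 0.33) by its brightest probe and up to 5.10 by another of its 3 probes, so its direction depended on the probe. ICS1, which makes the precursor of salicylic acid, was not well above background on any array and was not tested. The jasmonate marker VSP2 had -1.05 (SE 1.01, adjusted p = 0.537) and the defensin PDF1.2a 4.23 (SE 0.78, adjusted p = 0.0771, and 0.0228 with scan day as a block).

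Among the untreated arrays, array 2 read highest for PR1, PR2, PR5, CHI, PAD3, TI1 and EDS5, and lowest for FMO1 and SAG13. FMO1 was not well above background on any untreated array, so its rank there carries no weight. SAG13 differed little, with 0.98 on untreated array 2 against 1.03 and 1.33 on untreated arrays 1 and 3. PR1 read 2.41 on untreated array 2 against -2.43 and -3.77 on untreated arrays 1 and 3, and 4.22, 5.25 and 4.58 on the egg-deposited arrays. Within scan day 1, which holds untreated array 2, the median of the markers was 2.16, within scan day 2 it was 5.49, and within the shared slide 4.93. Without that array, 6 of the 9 tested markers rose (PR1, PR2, PR5, CHI, PAD3 and TI1), with a median log2 fold change of 4.90, and FMO1 did not pass (adjusted p = 0.0778).

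**Figure D2:**
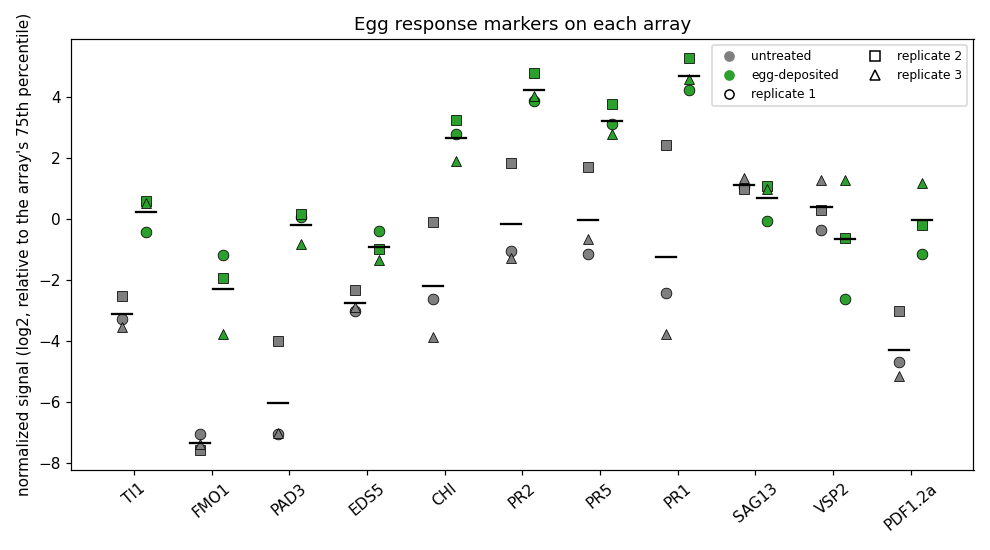
Normalized log2 signal (y axis, relative to the 75th percentile of each array) of the tested egg response markers, VSP2 and PDF1.2a on every array; grey is untreated, green egg-deposited, the symbol gives the replicate and each bar is a group mean. Untreated replicate 2 (grey squares) reads 2.41 for PR1, against -2.43 and -3.77 on the other untreated arrays.

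Genes of salicylic acid and systemic acquired resistance were higher as a group (32 tested of 35, median log2 fold change 1.68, camera adjusted p = 5.94e-10). With an estimated correlation the adjusted p was 0.446. Several of the egg response markers, PR1 among them, belong to this list as well, so the lists are not independent. In this list 2 genes rose, none fell and 30 did not pass, while 14 rose adjusted over the list alone. GRXC9, a glutaredoxin induced by salicylic acid, rose 4.28-fold (SE 0.23 on the log2 scale, adjusted p = 0.0306, 0.0707 with the replicate number as a block and 0.0862 with scan day as a block) and had a second probe at 4.25 on the log2 scale. The other riser was FMO1, and DMR6, a salicylic acid hydroxylase, had 3.29 (SE 0.63, adjusted p = 0.0806). The list's median signal was 1.15 on untreated array 2 and -0.25 and -0.69 on untreated arrays 1 and 3. The median difference was 0.49 within scan day 1, 2.19 within scan day 2 and 1.48 within the shared slide. Without untreated array 2, 8 members rose, among them PR1, DMR6, EDS1 and PAD4, and neither GRXC9 (adjusted p = 0.0578) nor FMO1 passed.

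Of the tryptophan and camalexin genes (13 tested of 15), 5 rose, none fell and 8 did not pass, while 7 rose adjusted over the list alone. The 5 were CYP71A13, CYP71A12, GSTF6 (5.99-fold, SE 0.29 on the log2 scale, adjusted p = 0.0306), CYP79B2 (log2 fold change 1.07, adjusted p = 0.0408, and 0.0580 with the replicate number as a block) and IGPS (1.91-fold, adjusted p = 0.0452, and 0.0683 with the replicate number as a block), which encode enzymes of this route. The median log2 fold change was 0.71 (camera adjusted p = 2.94e-07, and adjusted p = 0.43 with an estimated correlation), and 0.62 and 0.68 within scan days 1 and 2 and 0.48 within the shared slide. With scan day as a block none of the 5 passed (adjusted p from 0.0690 for CYP71A13 to 0.112 for IGPS, with 0.0808 for GSTF6 and 0.102 for CYP79B2). Without untreated array 2, 3 members rose, CYP71A13, GSTF6 and PAD3.

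Chitinases, enzymes that cut the chitin of fungi and arthropods, rose in 2 of 12 tested members (of 14), with none lower and 10 not passing. Adjusted over the list alone 8 rose and 1 fell. CHIC was at least 8.16-fold higher (adjusted p = 0.0255, 0.0603 with the replicate number as a block and 0.0665 with scan day as a block), and AT2G43620 at least 7.26-fold higher (adjusted p = 0.0487, and 0.107 with scan day as a block). EP3 had a log2 fold change of 2.52 (SE 0.44, adjusted p = 0.0719) and PR3 2.31 (SE 0.45, adjusted p = 0.0835). The median was 1.4 (camera adjusted p = 3.71e-04, and adjusted p = 0.43 with an estimated correlation), 1.04 and 1.75 within scan days 1 and 2 and 1.82 within the shared slide. Without untreated array 2, 1 member rose, CHI, while CHIC and AT2G43620 did not pass (adjusted p = 0.0508 and 0.0778).

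Endoplasmic reticulum folding genes, chaperones and helpers of secreted proteins, were all above 0 in log2 fold change, 16 of 16, and shifted as a group (median 1.37, camera adjusted p = 5.94e-10, and adjusted p = 0.43 with an estimated correlation). No single member passed over all genes, and 15 rose adjusted over the list alone. CRT3, a calreticulin, had 1.95 (SE 0.29, adjusted p = 0.0551), UTR3, a nucleotide sugar transporter, 1.39 (SE 0.26) and SHD, an endoplasmic reticulum HSP90 chaperone, 1.47 (SE 0.29). Within scan day 1, the single pair of untreated array 2 and egg-deposited array 3, the median was 0.41. It was 1.79 within scan day 2 and 1.92 within the shared slide, which is part of that day. Without untreated array 2, 2 members rose, CRT3 and BIP3. Heat shock genes were higher as a group too (9 tested of 11, median 1.64, camera adjusted p = 0.00550, and adjusted p = 0.466 with an estimated correlation), with no member past the threshold over all genes and 3 rising adjusted over the list alone. HSP17.4 had 2.39 (SE 0.40, adjusted p = 0.0707) and HSP90.1 2.57 (SE 0.73, adjusted p = 0.122), and the list median was 0.28 within scan day 1, 2.33 within scan day 2 and 2.28 within the shared slide. Egg-deposited array 3 stood apart, with a median heat shock signal of -2.99 against -0.42 and -1.43 on egg-deposited arrays 1 and 2 and -3.26, -3.22 and -3.30 on the untreated arrays.

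Photosynthesis genes were lower as a group and by little (54 tested of 54, median log2 fold change -0.24, camera adjusted p = 4.75e-06, and adjusted p = 0.639 with an estimated correlation). Of the random lists of matched signal, 3.87% had a lower median, and fry gave an adjusted p of 0.156. No member passed over all genes or adjusted over the list alone, and 53 of 54 were below 0. The largest evidence was for CHLM at -0.64 (SE 0.16, adjusted p = 0.109) and RBCS2B at -0.53 (SE 0.14, adjusted p = 0.118), genes of chlorophyll synthesis and of the small Rubisco subunit. The median was -0.02 within scan day 1, -0.34 within scan day 2 and -0.21 within the shared slide. Auxin, brassinosteroid and cell expansion genes were lower (18 tested of 18, median -0.65, camera adjusted p = 0.0498, and adjusted p = 0.639 with an estimated correlation), and no member passed over all genes. The brassinosteroid synthesis gene DWF4 had -1.43 (SE 0.28, adjusted p = 0.0831, and 0.0435 with the replicate number as a block), and EXPA5, an expansin, -0.97 (SE 0.25). The list median was -0.05 within scan day 1, -0.82 within scan day 2 and -0.65 within the shared slide, and the list did not pass with scan day as a block (adjusted p = 0.0506).

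Cell division genes (8 tested of 10, median 0.47, camera adjusted p = 0.0179, and adjusted p = 0.43 with an estimated correlation), phenylpropanoid and lignin genes (16 of 16, median 0.30, adjusted p = 0.0222, and adjusted p = 0.639 with an estimated correlation) and jasmonate genes (24 of 29, median 0.23, adjusted p = 0.0276, and adjusted p = 0.639 with an estimated correlation) were shifted upward, with no member past the threshold over all genes. Among them MCM2, a replication licensing gene, had 0.80 (SE 0.12, adjusted p = 0.0592), CCR2, of lignin synthesis, 1.19 (SE 0.18, adjusted p = 0.0592), and TAT3, a tyrosine aminotransferase induced by jasmonate, 4.69 (SE 0.86, adjusted p = 0.0769). The jasmonate median was 0.40 within scan day 1, 0.15 within scan day 2 and -0.10 within the shared slide. The cell division median was 0.45, 0.56 and 0.72, and the phenylpropanoid median 0.17, 0.41 and 0.41.

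The remaining 13 lists did not pass at the preset correlation. Aliphatic glucosinolate genes (22 tested, median 0.30) gave camera adjusted p = 0.0612, 0.0160 with the replicate number as a block and 0.0412 with scan day as a block, and passed in 10 of 17 refits. Their median was -0.24 within scan day 1, 0.52 within scan day 2 and 0.71 within the shared slide, so the direction turned within scan day 1. Indole glucosinolate genes (13 tested, median 0.16), in which CYP79B2 rose, gave 0.0746. Guard cell markers (7, median -0.41) gave 0.0512 and phloem and vein markers (8, median -0.23) 0.0846, and both passed with scan day as a block (adjusted p = 0.0412 for each). Flavonoid genes (11, median 0.42), proteinase inhibitors (8, median 0.25), in which TI1 rose, senescence genes (13, median 0.10) and pattern-triggered immunity genes (24, median 0.05) gave adjusted p of 0.233, 0.301, 0.301 and 0.433. Ethylene genes (17 tested, median -0.22), circadian clock genes (13, median -0.12) and reference genes (11, median -0.02) gave 0.493, 0.596 and 0.433, with means and tests directed upward while their medians were below 0. Abscisic acid genes (14, median 0.02) gave 0.746, with a mean and a test directed downward, and senescence genes had a mean of -0.02 with a median and a test directed upward. The defensin gene PDF1.2b of the ethylene list did not pass (adjusted p = 0.0707, and 0.0495 with the replicate number as a block). Epidermis and cuticle markers (6, median -0.16) gave 0.785. In all 11 of 24 lists were shifted at the preset correlation and none with an estimated correlation (camera, lowest adjusted p = 0.43; 1 list, tryptophan and camalexin, had an unadjusted p under 0.05). Without untreated array 2, 8 lists were shifted, and the phenylpropanoid (adjusted p = 0.118), cell division (0.0606) and auxin, brassinosteroid and cell expansion (0.0606) lists did not pass.

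**Figure D3:**
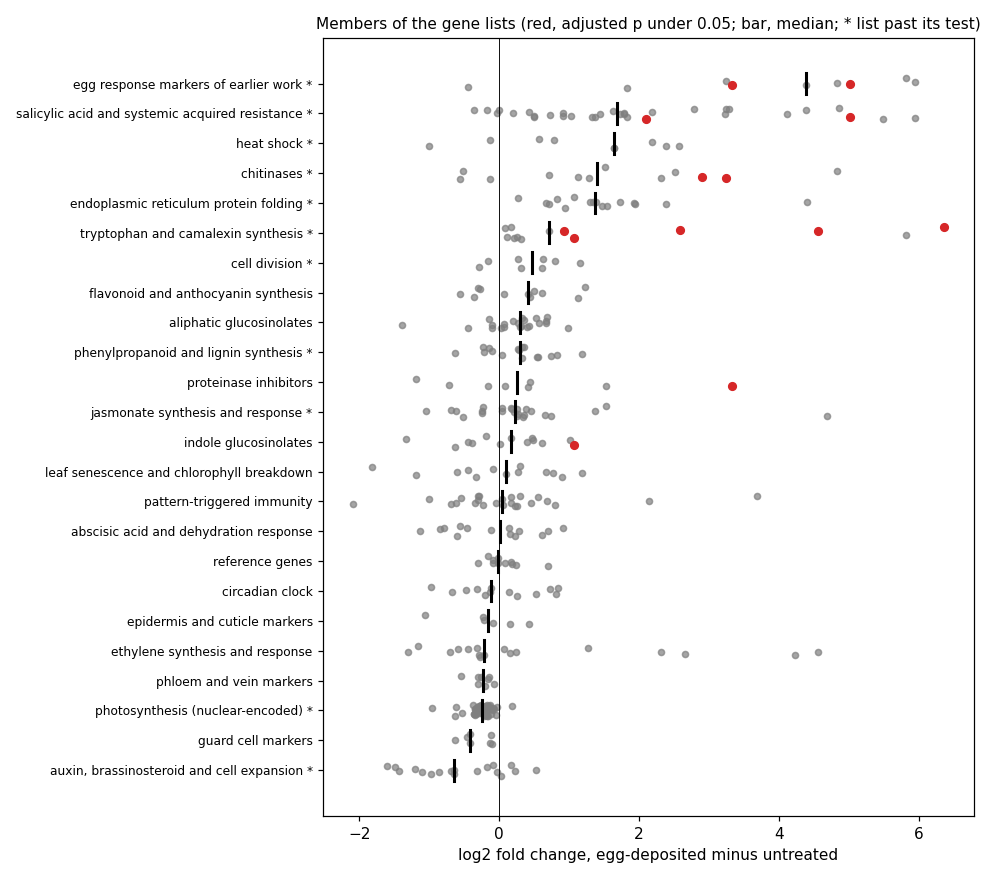
Log2 fold change, egg-deposited minus untreated (x axis), of the tested members of each of the 24 gene lists (1 list per line, points spread vertically for visibility). Red points passed an adjusted p of 0.05 over all genes, bars are medians, and a star marks the 11 lists past the camera test at the preset correlation, led by the egg response markers with a median of 4.39.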

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

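Within-batch list medians, list medians at lower bounds and list member counts without untreated array 2 were chosen after seeing the data; the other alternatives were fixed before the data were examined. Slide as a block was not run, since a fixed term leaves no residual degrees of freedom and a random one could not be estimated. Against 184 genes changed (162 higher, 22 lower, 164 at least 2-fold), normexp background correction gave 317 changed and 85 lower, quantile normalization 12 lower and median centring 9 lower. Without a filter on dim probes 49 changed (45 higher, 4 lower, 49 at least 2-fold). With a signal above background required on all 6 arrays none changed (0 higher, 0 lower, 0 at least 2-fold; limma, 4881 genes at an unadjusted p under 0.05), and the Welch-type test without moderation also gave 0 changed, 0 higher, 0 lower and 0 at least 2-fold (3288 at an unadjusted p under 0.05). The mean of all probes gave 41 lower, trend and robust eBayes 51 lower, and array weights 1810 changed (951 higher, 859 lower, 750 at least 2-fold). The replicate block gave 58 lower. Scan day as a block gave 49 changed (48 higher, 1 lower, 49 at least 2-fold). Leaving out each array in turn gave 30 to 281 changed, 29 to 216 higher, 1 to 148 lower and 30 to 274 at least 2-fold. The number of genes changed was 30 at adjusted p under 0.01 and 1102 at adjusted p under 0.1. Of 24 lists, 11 were shifted; leaving out each array gave 8 to 12, fry gave 3 and an estimated correlation between genes 0. Apart from the filter on all 6 arrays, under which 77 of the 184 genes were still tested, the cause of these changes was not tested. Every one of the 184 genes kept its direction wherever it was tested. Their groups did not overlap in the main fit, so leaving out 1 array could not turn a direction. The replicate and scan day blocks were balanced between the groups and left the fold changes as they were. A call lost with these blocks therefore came from the SE, the residual degrees of freedom or the adjustment, not from a smaller fold change.

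The jasmonate list turned from a median log2 fold change of 0.23 to -0.018 without egg-deposited replicate 3 and to -0.10 within the shared slide, and leaving out each array gave -0.018 to 0.33. The cause was not tested. The egg marker, salicylic acid, camalexin, chitinase, folding, photosynthesis and heat shock lists kept their direction and their call in all 17 refits at the preset correlation. All these refits assumed a correlation of 0.01, while the estimates ranged from 0.121 for the chitinase to 0.727 for the folding list. With fry the egg marker, camalexin and chitinase lists passed (adjusted p = 0.0347, 0.0224 and 0.0347). The salicylic acid, folding, photosynthesis and heat shock lists did not (0.0880, 0.0710, 0.156 and 0.0914). Over all lists, 428 values stayed alike, 22 became calls, 14 lost theirs, 38 uncalled or untested values moved and 2 reversed. For the named genes, 1774 values stayed alike, 269 lost and 78 gained a call, and 1 uncalled value, SAG13, changed sign. The replicate block changed no call of a list, or of a gene chosen by the rule for named genes, other than those printed. Among other genes named in the text, the replicate block ended the calls of IGPS, ASFT, ABCG16, ABCG18, ABCG20, AT3G22600, AT4G12490 and AT2G38390. Signal over background limits the 78 called genes that were dim on every untreated array to a lower bound of their fold.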

Other observations

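Among families named in the array annotation, 4 of 179 were enriched among the 162 higher genes (Fisher's exact test, one-sided, over families with at least 10 tested members). These families were tested after the largest rises had been seen, and neighbouring copies of a family are not independent. Lipid transfer and seed storage 2S albumin proteins held 10 of 51 tested members, against 0.42 by chance (adjusted p = 1.90e-09), among them EARLI1 and the neighbours AT3G22570, AT3G22580, AT3G22600 and AT3G22620. AT3G22142 of the same superfamily was among the called genes that fell (log2 fold change -1.43). With scan day as a block EARLI1, AT3G22580, AT3G22600, AT3G58550, AT4G12490 and AT4G12500 of the 10 did not pass (limma adjusted p from 0.0615 to 0.0873). Among them EARLI1, AT3G22600, AT3G58550 and AT4G12490 had a smaller SE with the block, and AT3G22580 a larger one. ABC-2 type transporters, which include exporters of wall and surface lipids, held 5 of 15 (ABCG1, ABCG6, ABCG16, ABCG18 and ABCG20, adjusted p = 9.06e-06). With scan day as a block only ABCG6 of these kept its call (limma adjusted p = 0.00886, and 0.0636 to 0.101 for the others). For ABCG1, ABCG16 and ABCG18 the block left a smaller SE (0.309, 0.276 and 0.121 against 0.312, 0.286 and 0.151). A larger SE therefore did not end their calls. For ABCG20 the SE was larger (0.590 against 0.548). Hydroxyproline-rich glycoproteins held 5 of 47 (adjusted p = 0.00249), with PELPK1, PELPK2 and AT4G38080, and peroxidases 4 of 28 (adjusted p = 0.00351), with PRX52. Of these, PELPK1 (limma adjusted p = 0.0571) and the peroxidase gene AT2G38390 (0.112) did not pass with scan day as a block, while the other called members did.

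Tests of the slide and of scan day, of related probes, and of untreated array 2 were chosen after the result was seen. The intervals given for medians from here on are over genes of the same arrays. These genes are not independent, so the intervals do not measure the spread between samples. Genes of suberin, the waxy polyester of roots and wounds, were a pattern seen in the largest rises: CYP86A1 was at least 26.4-fold, ABCG6 at least 18.3-fold and GPAT5 at least 7.97-fold higher (adjusted p = 0.00183 for each). This list, a Casparian strip list and a root list were written after values were seen: 6 of 15 tested suberin members rose and none fell (median 2.57), and 0 of 8 Casparian strip genes could be tested. The tables argue against root tissue in the samples, since 14 root-abundant genes (4 tested, none called), of which 5 had a signal above background on an untreated array, had a median log2 fold change of -0.33 (95% interval -0.69 to 0.05), and against a single transcript as the source of every rise, since the risers belonged to 5 gene families. Cross-reading within a family, such as ABCG6 and ABCG20, was not tested. Whether this may be part of a wider suberin response stays open, as the 10 tested members not seen beforehand had a median of 0.75 (-0.99 to 3.94), with ASFT and GELP51 rising. The filter left out other unseen members. Of these CYP86B1, FAR4, MYB41 and MYB53 were above background only on egg-deposited arrays (at least 3.47-fold, 2.01-fold, 1.45-fold and 2.45-fold higher), and 4 were dim on all arrays.

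The tables also argue against a slide difference as the cause for the 10 tested members that were above 1 in log2 fold change on the 4 arrays of the other slides: between the 2 arrays of the shared slide, a single pair, these had a median of 3.44 (1.96 to 5.02). Of these 10 members, 5 had first been noticed with all arrays. CYP86A1, GPAT5, ABCG2, ABCG6, ABCG20 and GELP51 among them were not well above background on any untreated array, so the size of their differences, and of this median, is not exact. An additive effect of scan day would cancel, because each day held as many arrays of both groups. Within scan day 1, a single pair of arrays, the 6 called members had a median of 3.82, the lower of the days (3.04 to 6.62). They were called on all arrays without overlap, so their rise within a day was fixed by that choice and decides nothing. With scan day as a block, ASFT (limma adjusted p = 0.0761) and ABCG20 (0.101) did not pass. CYP86A1, GPAT5, ABCG6 and GELP51 did (0.00758 to 0.0202). Over the whole list, including members that did not rise, the median was 2.27 within the shared slide (0.25 to 4.78), 0.76 within scan day 1 and 2.35 within scan day 2, so for its other members a slide difference stays open.

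Salicylic acid genes read higher on untreated array 2 than on untreated arrays 1 and 3, by a median of 1.19 on the log2 scale. If RNA of egg-deposited leaves had been mixed in, the list implied a share of 33.7%. The 102 genes outside the list that were called at least 8-fold higher without untreated array 2 also read higher on it, by a median of 1.42, but stood below the level this share would give (median gap -1.47, 95% interval -1.85 to -1.21). For this single array, this argues against such RNA as the whole cause, and a smaller share stays open. Egg-deposited array 3, scanned on the same day, did not share the rise (median difference from the other egg-deposited arrays -0.30, 95% interval -0.56 to 0.06), but as the only other array of that day it leaves an effect of scan day open. No biological explanation was tested, since the labels give none for this sample.

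The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 184 genes (1 of 10 splits reached that), and the highest other split 56. Among the 4 splits that part all 3 replicate pairs, the other 3 called 0 genes each with limma, and 459, 303 and 290 genes at an unadjusted p under 0.05, against 5003 for the real one. Of these 3, 1 also parts both scan days and 2 do not.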
